A study of Pan troglodytes with 50 samples.

How the data were processed

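Lentiviral massively parallel reporter assays were read in neural progenitors made from chimpanzee induced pluripotent stem cells. In this assay each test sequence drives a transcribed barcode from integrated lentiviral copies, and the RNA count of its barcodes over their DNA count measures its regulatory activity. The test sequences were human and chimpanzee alleles of human accelerated regions (HARs), conserved sequences that gained many substitutions on the human lineage. The lines were Pt2A and Pt5C, each from 1 chimpanzee, at stages N2 (neural progenitors per the labels) and N3 (glial progenitors per the labels). Of 42 reporter libraries, 24 held the HAR library in both lines and stages, 12 a permutation library in Pt2A at N2 and N3, and 6 a HAR control library in Pt2A at N2, always as 3 RNA and 3 DNA libraries per group. The labels state that 3 replicate cultures were infected separately, so p-values over cultures measure the spread between infections of 1 line. They do not measure the spread between animals. H3K27ac ChIP-seq peak lists, pooled over replicates, were given for Pt2A at N2 and N3.

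The authors deposited, for each reporter library, whole-number counts per 15-base barcode with the name of its element, and listed a barcode only where it was counted at least once. Per the labels' protocols a 10-base molecular identifier was added in the first PCR cycles, but whether the deposited counts are identifiers or reads is not stated, and how barcodes were assigned to elements is not given in the sources used here. Element coordinates come from the names in the files, and the submitters' processing notes name GRCh37 (hg19). Coordinates are given here 1-based on that build. The deposited peak lists give, per peak, a signal value of reads over background as the authors' caller wrote it, and a −log10 p and −log10 q. The caller and its version are not given in the sources used here. Chromosome names 2A and 2B show a chimpanzee assembly whose version is not stated, so peak positions were not set against the HAR coordinates, and no gene annotation of that assembly or of GRCh37 was used here.

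Counts were summed over the barcodes of an element in each library. Elements entered the tests with a mean of at least 10 barcodes per DNA library and after the filterByExpr filter of edgeR, which removed none. Activity is log2 of RNA over DNA, with TMM library factors, and its zero point is the median of the 120 elements that the files name as negative controls. Values per culture set each RNA library over the DNA library of the same replicate number, with a pseudocount of 0.5. Site effects and class means use a pseudocount of 1. Elements were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) in 1 fit per library with contrasts for line, stage, RNA and DNA, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Stage and line differences are contrasts of RNA over DNA between groups, centred by TMM. Stage and line effects on alleles are contrasts of allele differences.

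An allele difference was called only where both of 2 tests passed in the same direction. The first was the edgeR contrast of human RNA over DNA against chimpanzee RNA over DNA. The second was a two-sided permutation test that reassigned the barcodes of a pair between the alleles (at least 10 barcodes per allele, up to 100000 resamples, 10000 where no setting had p under 0.1). Every culture received the same barcoded copies, so the spread between cultures does not include the spread between barcodes of 1 sequence. Calls of activity, stage and line rest on the spread between cultures alone. Variants of the permutation library were tested in the same way against the chimpanzee sequence of their HAR, which all variants of a HAR share. Effects of single sites came from least squares of log2 RNA over DNA on the human or chimpanzee state of each site in each of 6 cultures, tested with limma 3.58.1 with stage as covariate. Classes of the HAR control library were compared with the rest by permutation (100000 resamples, exact for classes under 10 elements). Peak lists were overlapped with bedtools 2.31.1 by at least 1 base. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

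The tests, the named elements and most alternatives were fixed before the data were examined. Named were the 8 highest and 4 lowest HAR elements called in all 4 groups of the HAR library, and the pairs called in the mean of the 4 groups with 1 sign in all 12 cultures, up to 10 per direction. For each stage or line contrast the 4 largest calls per direction with cultures that do not overlap were named, and for alleles by stage or line the 3 largest per direction. In the permutation library these were the all-human variant of each HAR and up to 10 called sites by size, and in the HAR control library each class and the 3 highest elements. Given whatever their result were 2xHAR.20, 2xHAR.142, 2xHAR.164, 2xHAR.170, 2xHAR.183, 2xHAR.238 and 2xHAR.548. HAR1, HAR2 and ANC516 were also on that list but are not analysed here under those names. Items outside this rule are marked where they appear.

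The alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, a replicate block, limma on log2 ratios, removal of the barcode with the most RNA in each element, other zero points, a stricter peak list (−log10 q of at least 4), a reciprocal overlap, and the removal of each culture. In the alternatives to the count model the barcode test stayed as it was. Chosen after the data were seen were the N3 DNA libraries of the line as denominator for N2 RNA, the spread between barcodes or between variants as error, the negative controls as centre of stage and line differences, shuffled HARs as zero point, the mean of groups without Pt2A N2, and all alternatives for the allele differences of the HAR control library. The comparisons between libraries and the tests of site pairs were also chosen then.

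Activity, the Pt2A stage contrast, allele differences, sites and classes were tried on simulated data, with 200 changed elements or pairs and 20 changed of 41 sites. The line contrasts and the contrasts of alleles by stage or line were not. For activity in Pt2A N3 (2440 elements) the count model called 58.6% of elements changed by 0.1, 96.7% at 0.2 and 100.0% at 0.4 on the log2 scale, with 8 calls among 2240 unchanged. For the Pt2A stage contrast (2440 elements) it called 34.3%, 88.5% and 100.0%, with 4 calls among 2240 unchanged. For allele differences in Pt2A N3 (839 pairs) the count model alone called 40.6%, 90.4% and 100.0%, with 5 calls among 639 unchanged, and for the mean of the 4 groups 98.4%, 100.0% and 100.0%, with 8 calls among 639. In these simulations of the count model only cultures varied, so the rates of false calls leave out the spread between barcodes. With real barcodes shuffled between alleles, edgeR called a median of 420 of 839 pairs in the mean of the 4 groups. The barcode test alone, in Pt2A N3 (839 pairs), called 55.2% of differences of 0.2 and 98.1% of 0.4, with 9 calls among 639 unchanged. With the spread between barcodes as error, 65.6% and 99.1% of changes of 0.2 and 0.4 in Pt2A N3 activity were called, with 24 calls among 2240 unchanged. Of 41 sites, limma called 17 of 20 simulated effects and 2 of 21 unchanged sites, and the spread between variants called 12 of 20 and 0 of 21.

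A DNA library of the HAR library counted a median of 80 to 82 barcodes per element. The median standard error of an allele difference from the spread between barcodes was 0.0702 in Pt2A N2 and 0.0807 in Pt5C N3, while the median absolute allele difference was 0.0622 and 0.0732. Each pair of replicate libraries was compared by chi-square over elements, and none of the 42 pairs was identical (chi-square per degree of freedom from 1.06 to 108). The lowest value belonged to replicates 1 and 3 of the Pt2A N2 DNA of the HAR library, against 2.58 and 2.97 for the other 2 pairs of that group. Over single barcodes with at least 20 counts these 3 libraries differed by 1.04 to 1.06 per degree of freedom, against 1.42 to 10.7 in the other DNA groups. Of those, the Pt2A N2 DNA of the permutation library, on which its N2 results rest, gave 9.72 to 10.7 (22.1 to 108 over elements). The rest gave 1.42 to 1.91 over barcodes. The Pt2A N2 DNA libraries of the HAR library lie close to sampling noise, and this test cannot tell separate infections from repeat preparations of 1 pool of DNA. Whether they are separate infections stays open. They were kept as 3 replicates as the labels state, and the p-values of Pt2A N2 rest on that.

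Activity of HARs inside and outside H3K27ac peaks and peaks at promoters of gene lists were planned but not run, because they need the assembly and annotation of the peak lists. Input libraries of the ChIP-seq were not used here.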

Results

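The HAR library held 2440 elements and 205318 barcodes, with 1006 human and 996 chimpanzee alleles of 714 HARs, 173 HAR variants that combine human and chimpanzee bases, and positive and negative controls. Long HARs were covered by several overlapping tiles. Human and chimpanzee alleles formed 839 pairs in 606 HARs. It was read in 3 cultures of each of 4 groups, Pt2A N2, Pt5C N2, Pt2A N3 and Pt5C N3. Total counts per library ran from 6641422 to 16823119 for DNA and from 5410033 to 41867492 for RNA. The permutation library held 1049 elements (total counts from 7067408 to 44149144 in DNA and 15445752 to 26670905 in RNA). The HAR control library held 2590 elements (8649221 to 9464926 in DNA and 24263262 to 25951194 in RNA) and used 202032 of the barcodes of the HAR library, while the permutation library shared 0 barcodes with it.

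The activity of each element in each line and stage was asked first. The most active HAR element called in all 4 groups was tile 1 of 2 of the human allele of 2xHAR.548 (chromosome 3, 70655294 to 70655464, GRCh37/hg19, 1-based as all positions here), with a log2 RNA over DNA of 1.15 ± 0.34 (SD, n = 12 cultures). Both alleles of HAR156 (chromosome 8, 116791662 to 116791832) followed, at 1.02 ± 0.62 for chimpanzee and 0.91 ± 0.53 for human, with the chimpanzee allele at 1.65 ± 0.038 in Pt5C N3 but 0.61 ± 0.023 in Pt2A N2 and 0.31 ± 0.069 in Pt2A N3 (n = 3 each). The human allele of 2xHAR.10 (chromosome 2) reached 0.85 ± 0.41 in tile 1 and 0.83 ± 0.43 in tile 2, its chimpanzee tile 2 reached 0.72 ± 0.36, and 2xHAR.176 (chromosome 4, 146403095 to 146403265) reached 0.80 ± 0.36 for human and 0.75 ± 0.37 for chimpanzee. Below the negative controls in all 4 groups lay HAR76 tile 1 of 3 (chromosome X, 85465762 to 85465932), at −0.28 ± 0.078 for human and −0.24 ± 0.083 for chimpanzee, 2xHAR.317 chimpanzee (chromosome 15, 91009515 to 91009685) at −0.27 ± 0.13, and 2xHAR.39 chimpanzee tile 2 (chromosome 2, 21475371 to 21475541) at −0.24 ± 0.079. The low call of 2xHAR.317 was lost in Pt2A N2 (−0.064 against −0.47) when N2 RNA was set against the N3 DNA of the line.

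Across all elements, edgeR called 679 higher and 818 lower than the negative controls in Pt2A N2, 752 and 677 in Pt5C N2, 892 and 705 in Pt2A N3, and 919 and 868 in Pt5C N3, of 2440 tested. Human HAR alleles were called higher in 26.3%, 32.6%, 37.8% and 40.0% of cases in these 4 groups, and chimpanzee alleles in 27.6%, 31.0%, 37.2% and 38.2%. The 120 negative controls were called higher in 27.5%, 22.5%, 29.2% and 30.8%, and the 124 elements named as H3K27ac positive controls in 38.7%, 34.7%, 41.9% and 43.5%. The difference between these classes was not tested in the HAR library. In all 4 groups 235 elements were called higher and 194 lower, and 119 HARs had an allele among the former. Of 2002 HAR alleles 172 were called higher in all 4 groups, and 450 in the 3 groups other than Pt2A N2. With the TMM centre as zero point, calls split into 768 higher and 732 lower in Pt2A N2, 750 and 681 in Pt5C N2, 797 and 806 in Pt2A N3, and 927 and 854 in Pt5C N3, so which direction prevailed in Pt2A depended on the zero point. With the spread between barcodes as error, they fell to 314 higher and 545 lower in Pt2A N2, 416 and 313 in Pt5C N2, 581 and 338 in Pt2A N3, and 684 and 490 in Pt5C N3. With N3 DNA as denominator they numbered 490 and 754 in Pt2A N2 and 869 and 843 in Pt5C N2.

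HARs fixed in advance differed widely. 2xHAR.548 tile 2 was at 0.72 ± 0.54 for human and 0.23 ± 0.17 for chimpanzee (SD, n = 12 cultures), and 2xHAR.183 (chromosome 2, 11531871 to 11532041) at 0.57 ± 0.47 and 0.51 ± 0.42. 2xHAR.238 (chromosome 2) was called higher in all 4 groups, with its 2 human tiles at 0.41 ± 0.14 and 0.40 ± 0.15 and the chimpanzee sequence at 0.17 ± 0.043. These tiles and the chimpanzee sequence were not matched as pairs, so no allele test was run. 2xHAR.142 (chromosome 14, 34048648 to 34048818), which lies in an intron of NPAS3, a transcription factor of neurons, was lower than the negative controls for human (−0.16 ± 0.056) and chimpanzee (−0.14 ± 0.039) in all 4 groups. 2xHAR.20, near EN1, was highest in tile 4, at 0.29 ± 0.14 for human and 0.19 ± 0.15 for chimpanzee, the latter not called in Pt2A N2. 2xHAR.164 (0.055 ± 0.072 human, 0.097 ± 0.083 chimpanzee) and 2xHAR.170 (0.11 ± 0.092 and 0.048 ± 0.066) were called higher in Pt2A at both stages and in Pt5C at neither. The difference between lines for these HARs is not given by those calls.

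The Pt2A N2 group of the HAR library stood apart from the other groups of that library and from the HAR control library. Over 2440 elements, activity in Pt2A N2 correlated with Pt5C N2 at r = 0.269, with Pt2A N3 at 0.105, with Pt5C N3 at 0.0377 and with the HAR control library, read in the same line and stage, at −0.109. The other groups correlated with each other at 0.736 (Pt5C N2 with Pt2A N3), 0.905 (Pt5C N2 with Pt5C N3) and 0.793 (Pt2A N3 with Pt5C N3). Replicate cultures of Pt2A N2 correlated at 0.941 to 0.952, and those of Pt5C N2 at 0.727 to 0.946, where replicate 3 stood apart. The activity of Pt5C N2 replicate 3 correlated with Pt2A N2 at 0.616, against 0.129 for the mean of its other replicates. Its RNA alone correlated with Pt2A N2 RNA at 0.921 and with replicates 1 and 2 of its own group at 0.884, and its DNA deviation from N3 DNA followed that of Pt2A N2 at 0.925. Without this culture 906 elements in place of 752 were called higher in Pt5C N2. Set against the N3 DNA of the line, Pt2A N2 RNA gave r = 0.733 with Pt5C N2, 0.696 with Pt5C N3 and 0.587 with the HAR control library, none of which shares a sequenced library with it. Over their own DNA, the other groups correlated with the HAR control library at 0.794 (Pt5C N2), 0.743 (Pt2A N3) and 0.881 (Pt5C N3). Pt2A N2 thus stayed the lowest of the groups with N3 DNA as well. The permutation library, which shares 0 barcodes with the HAR library, correlated over 438 shared elements with Pt2A N2 of the HAR library at 0.860 for its N2 activity and at 0.733 for its N3 activity, and at 0.680 between the N3 activities of both. The N2 DNA of both libraries shared their deviation from N3 DNA at 0.93. Over N3 DNA in both, their Pt2A N2 activities correlated at 0.74. Elements are not independent replicates, so these are descriptions without p-values.

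**Figure D1:**
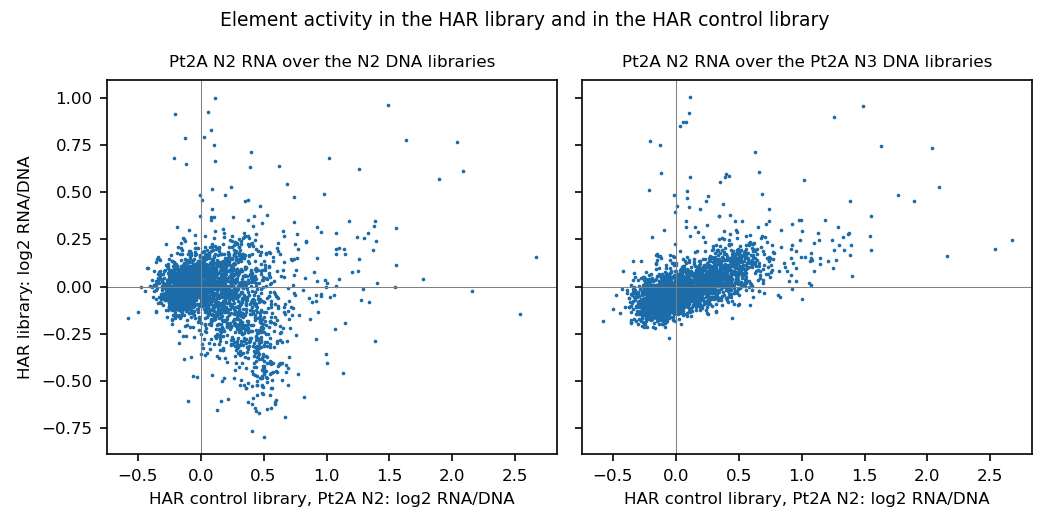
Log2 RNA over DNA of the 2440 elements in the HAR library in Pt2A N2 (vertical axes) against the HAR control library in the same line and stage (horizontal axes), 1 point per element. With the N2 DNA libraries as denominator r is −0.109, and with the Pt2A N3 DNA libraries 0.587.

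Human and chimpanzee alleles of the same HAR were then compared. In the mean of the 4 groups the human allele was higher for 2xHAR.10 tile 1 (chromosome 2, 113992950 to 113993120) by 0.49 ± 0.21 and for 2xHAR.548 tile 1 by 0.48 ± 0.23 on the log2 scale (SD, n = 12 cultures), although the latter was not called in Pt5C N2 (0.15). Smaller gains of the human allele were found for HAR183 tile 2 (chromosome 17, 6050406 to 6050576; 0.24 ± 0.075), 2xHAR.520 tile 1 (chromosome 3, 161591807 to 161591977; 0.24 ± 0.14), 2xHAR.424 tile 3 (0.23 ± 0.19) and 2xHAR.127 tile 1 (0.19 ± 0.061). The human allele was lower for 2xHAR.518 (chromosome 14, 80280283 to 80280453; −0.36 ± 0.12), 2xHAR.401 (chromosome 17, 5667563 to 5667733; −0.30 ± 0.36), 2xHAR.385 tile 2 (−0.28 ± 0.12) and 2xHAR.534 (−0.28 ± 0.11). The naming rule required 1 sign in all 12 cultures, which 10 of the 14 pairs called in the mean and 154 of all 839 pairs had. The difference of 2xHAR.401 was −0.90 ± 0.071 in Pt2A N3 and −0.048 to −0.16 in the other groups, where it was not called. By single group, HAR183 tile 2, 2xHAR.424 tile 3 and 2xHAR.534 were called in both groups of Pt5C and in neither of Pt2A. 2xHAR.127 tile 1 was called in Pt5C N2 alone. Such calls do not test a difference between lines. 2xHAR.10 tile 1 and 2xHAR.518 were the only 2 pairs called in all 4 groups.

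In the mean of the 4 groups 14 of 839 pairs passed both tests, 7 higher and 7 lower in human. The edgeR test alone called 458 pairs, and the barcode permutation test gave 101 at an unadjusted p under 0.05. Adjusted p-values of the barcode test for the named pairs ran from 0.00168, for 2xHAR.10, 2xHAR.548, 2xHAR.518 and 2xHAR.401, to 0.0336 for HAR183 and 2xHAR.127. By group, 39 pairs were called in Pt2A N2 (16 higher in human), 28 in Pt5C N2 (15), 24 in Pt2A N3 (11) and 24 in Pt5C N3 (13), with 246, 221, 250 and 266 by edgeR alone. Without 1 culture edgeR alone called 135 to 185, 107 to 198, 151 to 179 and 162 to 193 in these groups, and the lowest counts came without Pt2A N2 replicate 2, Pt5C N2 replicate 2, Pt2A N3 replicate 3 and Pt5C N3 replicate 1. Counts of 152 without Pt2A N2 replicate 1, 137 without Pt5C N2 replicate 1, 154 without Pt2A N3 replicate 1 and 172 without Pt5C N3 replicate 2 were also lower by more than 1.5 times. In at least 1 group 81 pairs were called, in 2 or more 22 and in 3 or more 10. With N3 DNA as denominator the Pt2A N2 calls fell to 11, and without Pt2A N2 the mean gave 26 calls, which included 13 of the 14. 2xHAR.127 lost its call with N3 DNA (adjusted barcode p = 0.101, permutation test), without its strongest barcode, and without any of 3 cultures (Pt5C N2 replicate 1, Pt2A N3 replicate 2 or Pt5C N3 replicate 3). HAR183 lost its call without Pt5C N2 replicate 1 or Pt5C N3 replicate 1. The difference of 2xHAR.127 was 0.15 with N3 DNA and 0.18 without its strongest barcode. Without 1 culture it ran from 0.18 to 0.20, and that of HAR183 from 0.23 to 0.26. Removal of 1 culture took the Pt5C N2 calls to 13 (replicate 1) or 16 (replicate 2) and the Pt2A N3 calls to 15 (replicate 2).

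Of the HARs fixed in advance, 2xHAR.548 tile 2 was called in the mean (0.49 ± 0.41, higher in human in 11 of 12 cultures), from 0.050 ± 0.10 in Pt2A N2 to 1.07 ± 0.032 in Pt2A N3. With N3 DNA its Pt2A N2 difference was 0.44 and was called. 2xHAR.142 (−0.019 ± 0.032), 2xHAR.164 (−0.042 ± 0.062), 2xHAR.170 (0.060 ± 0.055) and 2xHAR.183 (0.061 ± 0.054) were not called in any group or in the mean. 2xHAR.20 was called only in tile 3 in Pt5C N3 (−0.34 ± 0.0082, n = 3, adjusted permutation p = 0.0325). In the mean its tiles 1 to 4 gave 0.080, 0.11, −0.19 and 0.11, none called.

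**Figure D2:**
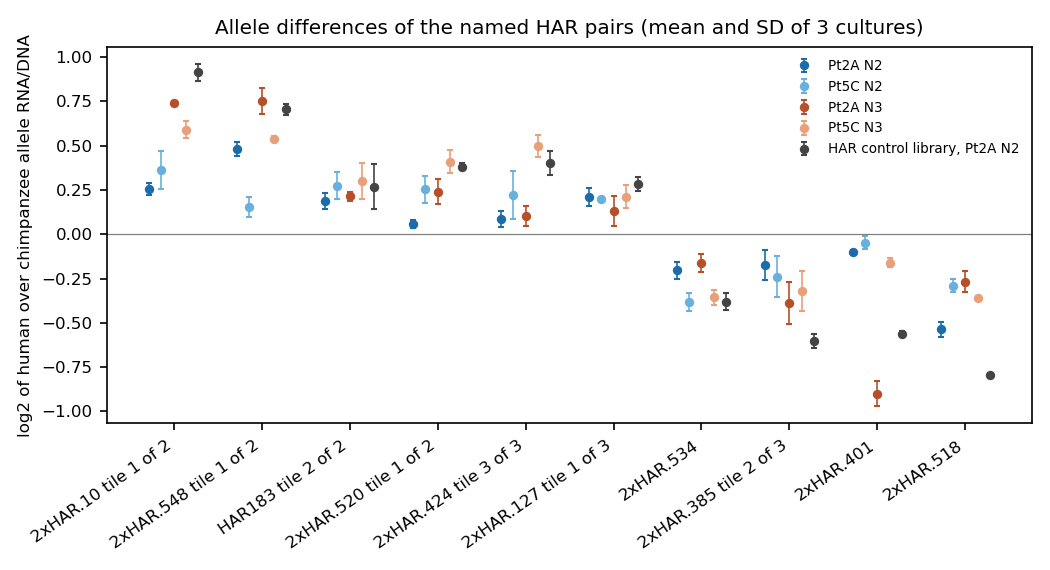
Log2 of human over chimpanzee activity of the 10 named pairs in the 4 groups of the HAR library and in the HAR control library (Pt2A N2). Points are means and bars SDs of 3 cultures. 2xHAR.401 lies at −0.90 in Pt2A N3 and between −0.16 and −0.048 in the other groups of the HAR library.

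Between stages, with values centred over all elements by TMM, activity in Pt2A was higher at N3 than at N2 for the human tile 2 of 2xHAR.548 (1.39 ± 0.098 against 0.054 ± 0.11, n = 3 each), the chimpanzee allele of 2xHAR.348 (chromosome 2, 190306145 to 190306315; 1.02 ± 0.029 against −0.20 ± 0.033) and both alleles of 2xHAR.275 (chromosome 17, 3417157 to 3417327; human 0.89 ± 0.039 against −0.27 ± 0.11). It was lower at N3 for human 2xHAR.279 (chromosome 17, 73753546 to 73753716; −0.013 ± 0.028 against 1.01 ± 0.040), both alleles of 2xHAR.267 tile 2 (chimpanzee −0.033 ± 0.035 against 0.92 ± 0.021) and human 2xHAR.403 tile 2 (0.068 ± 0.037 against 0.94 ± 0.021). With N3 DNA in both stages these calls were kept. In the HAR control library, read in Pt2A at N2 and compared after these results were seen, all 8 lay nearer to their Pt2A N3 than to their Pt2A N2 activity. Values there were 1.77 for 2xHAR.548 tile 2, 0.63 for 2xHAR.348, 0.92 for human 2xHAR.275, 0.11 for 2xHAR.279, −0.20 for chimpanzee 2xHAR.267 and 0.055 for 2xHAR.403, so these differences may belong to the Pt2A N2 libraries of the HAR library and not to the stage. With N3 DNA the rise of 2xHAR.548 tile 2 was 0.89 in place of 1.34 and that of human 2xHAR.275 0.67 in place of 1.16, while 2xHAR.279 fell by 1.03 in place of 1.02. In Pt5C the human tile 1 of 2xHAR.10 (0.57), the human tile 1 of 2xHAR.548 (0.55) and both alleles of 2xHAR.176 (0.50 human, 0.48 chimpanzee) rose from N2 to N3. Their SDs over cultures were 0.21 to 0.27 at N2, where replicate 3 stood apart, and 0.019 to 0.035 at N3. Chimpanzee 2xHAR.49 tile 1 (−0.36), human 2xHAR.121 tile 3 (−0.27), chimpanzee 2xHAR.261 (−0.18) and chimpanzee 2xHAR.432 (−0.18) fell. 2xHAR.432 was no longer called without Pt5C N2 replicate 3 (−0.089) or without N3 replicate 1, 2 or 3 (−0.19, −0.18 and −0.19), nor 2xHAR.49 without Pt5C N3 replicate 2 (−0.35), and with N3 DNA the fall of 2xHAR.261 was −0.076 and that of 2xHAR.432 −0.12.

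The edgeR contrast called 1641 elements in Pt2A (790 higher and 851 lower at N3) and 425 in Pt5C (300 and 125) of 2440. Centred on the negative controls, the Pt2A calls split into 883 higher and 621 lower. With N3 DNA in both stages 1323 were called in Pt2A, of which 895 were shared in the same direction, and 324 of the 1641 changed sign. In Pt5C 530 were then called, 273 shared, and 17 of the 425 changed sign. Over elements, the stage change of Pt5C correlated with that of Pt2A at 0.69 with own DNA and at 0.4 with N3 DNA in both. Pt5C N2 replicate 3 shared the DNA deviation of Pt2A N2 (0.925), so these values cannot separate the stage from the N2 libraries. Over all 2440 elements, called or not, the cultures of the stages did not overlap in 73.0% in Pt2A and 33.0% in Pt5C, where chance gives 10%. Without Pt5C N3 replicate 2 the Pt5C count was 246.

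Between lines at N2, Pt5C exceeded Pt2A for chimpanzee HAR156 (by 0.92, from 0.62 ± 0.023 in Pt2A, n = 3 each), an H3K27ac positive control (chromosome 5, 107273101 to 107273271; 0.84 ± 0.31 against −0.034 ± 0.029), human 2xHAR.183 (0.76 ± 0.31 against −0.067 ± 0.053) and chimpanzee HAR125 (0.54 ± 0.28 against −0.27 ± 0.077). The difference of HAR125 was 0.82, and 0.52 with N3 DNA. Pt2A exceeded Pt5C for both alleles of 2xHAR.267 tile 2 (human −0.59, chimpanzee −0.58 as Pt5C minus Pt2A), human 2xHAR.403 tile 2 (−0.58) and human 2xHAR.279 (−0.53). In the HAR control library, also read in Pt2A at N2, these elements lay at −0.13, −0.20, 0.055 and 0.11. All were nearer there to their Pt2A N3 than to their Pt2A N2 activity. These differences may thus belong to the Pt2A N2 libraries of the HAR library and not to the line. At N3 both alleles of HAR156 again stood higher in Pt5C (1.35 chimpanzee, 1.16 human), as did the same H3K27ac control (1.07) and chimpanzee 2xHAR.9 (0.64). Higher in Pt2A were chimpanzee 2xHAR.348 (−0.70), an H3K27ac positive control (chromosome 10, 79606901 to 79607071; −0.69), chimpanzee 2xHAR.401 (−0.66) and an ENCODE negative control (chromosome 2, 97532801 to 97532971; −0.51). edgeR called 1447 elements at N2 (722 higher in Pt5C, 725 in Pt2A) and 560 at N3 (328 and 232). Over all elements the cultures of the lines did not overlap in 65.1% at N2 and 39.8% at N3, where chance gives 10%. With N3 DNA the N2 count was 673, and 220 of the 1447 changed sign. Centred on the negative controls, the N2 calls split into 751 higher in Pt5C and 605 in Pt2A, and the N3 calls into 264 and 346. With DESeq2 the N2 split was 741 and 607. Each line comes from 1 individual, so these contrasts compare 2 lines and not individuals in general.

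The allele difference itself was compared between stages and lines. In the HAR library the human advantage of 2xHAR.548 tile 2 was 0.17 ± 0.19 at N2 and 0.81 ± 0.29 at N3 (SD, n = 6 cultures each; edgeR adjusted p = 3.16e-10), and the human deficit of 2xHAR.401 was −0.076 ± 0.039 and −0.53 ± 0.41 (adjusted p = 1.21e-13). The human deficit of 2xHAR.432 (chromosome 18, 62021340 to 62021510) was −0.46 ± 0.18 at N2 and −0.064 ± 0.11 at N3 (adjusted p = 1.90e-07). These 3 kept their calls with N3 DNA, with stage differences of 0.37, −0.44 and 0.34, the first of which had been 0.64. 2xHAR.510 (0.38), 2xHAR.205 tile 1 (−0.36) and 2xHAR.556 (−0.35) lost theirs with N3 DNA, at 0.099, −0.036 and −0.063 (edgeR adjusted p = 0.134, 0.680 and 0.141). In the HAR control library, in Pt2A at N2, all 6 lay nearer to their Pt2A N3 than to their Pt2A N2 difference, a comparison made after these results were seen. They were at 1.07 ± 0.064 (2xHAR.548 tile 2), −0.56 ± 0.017 (2xHAR.401), −0.015 ± 0.049 (2xHAR.432), 0.10 ± 0.050 (2xHAR.510), −0.20 ± 0.076 (2xHAR.205 tile 1) and −0.51 ± 0.064 (2xHAR.556, SD, n = 3 cultures), so the stage may not be the cause of these differences. Between lines, the human deficit of 2xHAR.401 was −0.50 ± 0.44 in Pt2A and −0.10 ± 0.068 in Pt5C, and the allele difference of 2xHAR.9 (chromosome 20, 708949 to 709119) was 0.029 ± 0.091 in Pt2A and −0.42 ± 0.13 in Pt5C. 2xHAR.270 tile 1 (0.35 as Pt5C minus Pt2A) and 2xHAR.234 tile 2 (−0.34) also differed, and all 4 were still called with N3 DNA. 2xHAR.199 (0.35) and 2xHAR.411 tile 1 (−0.34) were not, at 0.11 and −0.20 (edgeR adjusted p = 0.615 and 0.0629). In all, edgeR called 104 of 839 pairs by stage (56 higher at N3) and 75 by line (42 higher in Pt5C). The line count was 12 with N3 DNA and 45 without Pt2A N2 replicate 2, and the stage count was 70 with N3 DNA and 69 without that culture.

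The permutation library asked which human substitutions change the activity of 7 HARs, with every combination of human and chimpanzee bases at 3 to 9 sites. None of the all-human variants was called against the chimpanzee sequence at either stage. At N2 they lay between −0.063 ± 0.0088 for 2xHAR.65 tile 1 and 0.10 ± 0.041 for 2xHAR.170 (SD, n = 3 cultures), and at N3 between −0.036 ± 0.018 for 2xHAR.65 tile 2 and 0.067 ± 0.031 for HAR34. 2xHAR.1, with 512 combinations of 9 sites, ranged from −0.32 to 0.21 at N2 and from −0.17 to 0.16 at N3. Of 8 human tiles of HARE5, an enhancer near FZD8, none was called, with differences from −0.099 to 0.10 at N2 and −0.13 to 0.23 at N3. Both tests together called 0 of 768 comparisons at either stage, which are 760 variants and the 8 tiles of HARE5. edgeR alone called 284 at N2 (217 higher, 282 of them variants) and 39 at N3 (26 higher, 35 of them variants), with 353 and 153 at an unadjusted p under 0.05, and DESeq2 called 274 and 26. The barcode test alone called 0, with 43 and 11 at an unadjusted p under 0.05 and smallest adjusted p of 0.115 and 0.996 (permutation tests). With N3 DNA edgeR called 35 at N2. Without 1 culture edgeR called 193 (without Pt2A N2 replicate 3) to 383 at N2, and at N3 7, 1 and 6 without replicates 1, 2 and 3, against 39 with all. The signs of several of these uncalled all-human differences depended on the setting.

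Averaged over all backgrounds, single sites had small effects. The human base raised activity at C69T of 2xHAR.170 (0.087 ± 0.043, SD, n = 6 cultures), G95C (0.036 ± 0.016), A88T (0.034 ± 0.036) and G117C (0.031 ± 0.0086) of 2xHAR.1, and T43A of 2xHAR.164 (0.030 ± 0.013). It lowered activity at T73G of 2xHAR.170 (−0.054 ± 0.027), at A94G (−0.027 ± 0.0040), C55T (−0.025 ± 0.020) and C119G (−0.021 ± 0.0058) of 2xHAR.1, and at A14G of 2xHAR.65 tile 2 (−0.021 ± 0.0042). Tokens give the chimpanzee base, the position and the human base, numbered as in the files, where the origin of the count is not stated. Each named site had 1 sign in 6 of 6 cultures. limma called 23 of 41 sites (10 higher and 13 lower with the human base), and against the spread between variants 9 were called, 7 in 2xHAR.1 and 2 in 2xHAR.142. By that error the sites of 2xHAR.170, 2xHAR.164 and 2xHAR.65 were not called. With N3 DNA 26 were called and 5 of the 23 changed sign. A88T (−0.0030) and C55T (0.00055) were then not called (limma adjusted p = 0.0733 and 0.614). The other 3, singled out after their values were seen, were called in the opposite direction. They were C91T of 2xHAR.142 (0.018 to −0.012), G33T of 2xHAR.1 (−0.011 to 0.0027) and A66G of 2xHAR.238 (−0.012 to 0.0065), and C91T was 1 of the 9. Of these 9 only 4, A94G, G95C, G117C and C119G of 2xHAR.1, were called in the same direction with N3 DNA, and neither site of 2xHAR.142 was. A36T of 2xHAR.1 (0.017 to 0.0022) and T134C of 2xHAR.142 (−0.020 to −0.0014), also singled out then, lost their calls (limma adjusted p = 0.0665 and 0.134). The effect of G95C was 0.020 with N3 DNA. For 17 sites the effect differed between stages over the DNA of each stage (limma), among them A88T and C55T. This contrast is not given with N3 DNA, so it cannot separate the stage from the N2 DNA libraries.

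**Figure D3:**
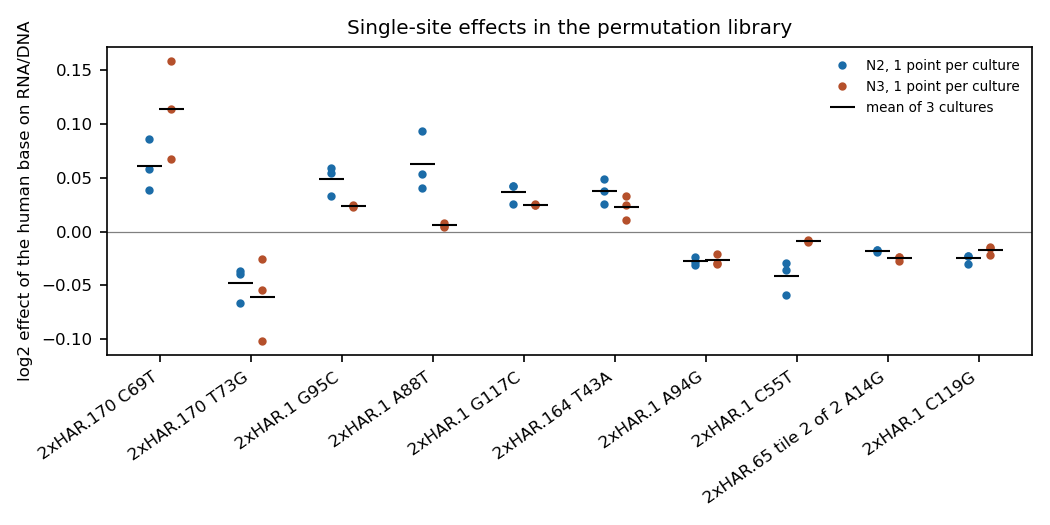
Effect of the human base on log2 RNA over DNA at the 10 named sites of the permutation library, 1 point per Pt2A culture (3 at N2, 3 at N3) with bars at the mean of 3 cultures. Effects of 2xHAR.1 A88T are 0.063 at N2 and 0.0060 at N3, each over the DNA of its stage. With N3 DNA in all cultures its mean effect is −0.0030.

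Between N2 and N3, 260 of 1049 elements of the permutation library differed in activity (178 higher and 82 lower at N3, edgeR). The split depended on the centre, with 90 higher and 192 lower when the negative controls were centred, 135 and 125 with DESeq2, and 113 and 116 with its size factors in edgeR. Without 1 culture the count ran from 45 (without Pt2A N3 replicate 2) to 317, and was 137 without Pt2A N2 replicate 3, 111 without Pt2A N3 replicate 1 and 94 without Pt2A N3 replicate 3. With N3 DNA in both stages it was 214 (131 higher and 83 lower). The N2 DNA libraries deviated from N3 DNA by SDs of 0.0948 to 0.179 over elements, against 0.0295 to 0.0327 for single N3 DNA libraries. The count of 260 therefore cannot separate the stage from the N2 DNA libraries.

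The HAR control library was read in Pt2A N2 and adds 150 shuffled HAR sequences. Its most active elements were 2xHAR.392 (chromosome 18, 7442533 to 7442703), at 2.67 ± 0.050 for the chimpanzee and 2.54 ± 0.045 for the human allele (SD, n = 3 cultures), and an H3K27ac positive control (chromosome 14, 56424701 to 56424871) at 2.16 ± 0.059. edgeR called 1370 elements higher and 863 lower than the negative controls of 2590, against 1117 and 1119 from the TMM centre and 837 and 1463 when the shuffled HARs, whose median lay 0.16 above the negative controls, were the zero point. Shuffled HARs were called active in 71.3% of cases, human alleles in 54.5%, chimpanzee alleles in 53.7%, H3K27ac positive controls in 61.3% and the 120 negative controls in 42.5%. Of 13 classes 1 differed from the rest, the 173 HAR variants, by −0.20 ± 0.0082 (permutation adjusted p = 0.00013, raw p = 1e-05, the smallest the resamples can give). These variants are combinations of the sites of only 4 HARs, most of them of 2xHAR.142, so they are not independent members and the p-value is too small to that extent. Human HAR alleles lay 0.029 above the rest (adjusted p = 0.142), chimpanzee alleles 0.016 (0.335), H3K27ac positive controls 0.055 (0.179) and shuffled HARs 0.050 (0.179, all by permutation). With the median over barcodes 2 classes were called, the shuffled HARs joining at 0.071. The negative control classes marked H3K27me3 lay at −0.10 (N2), −0.090 (AP) and −0.074 (N1), ENCODE negative controls at −0.060, ENCODE positive controls at 0.077 and EnhancerFinder positive controls at 0.015, none called. The remaining pair of classes, of 2 elements each, lay at 0.034 (positive) and 0.016 (negative), and were not called either. Set against their own shuffled sequence, human alleles differed by −0.0097 (150 pairs, permutation p = 0.767) and chimpanzee alleles by −0.0052 (129 pairs, permutation p = 0.894).

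In this library 124 of 839 pairs passed both allele tests, 62 higher and 62 lower in human (399 by edgeR alone, 301 to 335 without 1 culture), with a median absolute difference of 0.25 among calls. All 10 named pairs were called with the same sign as in the HAR library, with 0.91 ± 0.047 for 2xHAR.10 tile 1 and −0.79 ± 0.0085 for 2xHAR.518 (SD, n = 3 cultures). Of the 14 calls in the mean of the HAR library 13 were among the 124, and of the 26 without Pt2A N2, 25. Of the 39 calls of Pt2A N2 in the HAR library, 18 had the same sign in this library and 6 were called, against 24 and 22 of the 24 calls of Pt5C N3. As the libraries share most barcodes, these overlaps are not independent of barcode effects.

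H3K27ac marks active enhancers and promoters. The pooled peak lists of Pt2A held 102693 peaks at N2 (median width 894 bases, 169 Mb covered) and 89425 at N3 (988 bases, 147 Mb). Of the N2 peaks 52217 (50.8%) overlapped an N3 peak by at least 1 base, and of the N3 peaks 52798 (59.0%) an N2 peak. Shared peaks had a higher median signal in the authors' values, 4.84 against 2.82 at N2 and 5.44 against 2.78 at N3. The lists reach down to a −log10 p of 2.00 at both stages, so they hold weak peaks. In the stricter list 67454 peaks at N2 and 63077 at N3 remained, of which 55.7% and 60.7% were shared. With a reciprocal overlap the shared N2 peaks numbered 27187 (26.5%). There was 1 pooled list per stage, so no difference between stages was tested.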

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

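Of the tests in this part, those of the Pt2A N2 denominator, of the HAR control and permutation libraries and of RNA against DNA shifts were chosen only after the result was seen, as was the use of N3 DNA for N2 RNA.

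Activity differed between groups, by a test of the difference itself, for 1641 elements between stages in Pt2A, 425 between stages in Pt5C, 1447 between lines at N2 and 560 between lines at N3, and for 260 elements between stages in the permutation library. With 3 cultures against 3, the 10 splits are too few for a share under 0.05, and the highest count of another split was 0 for each of these 5. The allele difference itself differed by stage for 104 pairs, led by 2xHAR.548 tile 2 and 2xHAR.401, and by line for 75, led by 2xHAR.9 and 2xHAR.401. For both, 1 of 100 splits, the real one, gave as many, and the highest others gave 49 and 31. Chance in how cultures fall into groups is excluded by this only if all cultures are separate infections, which stays open for the Pt2A N2 DNA. Such splits do not test differences between barcodes, which all cultures share. With N3 DNA the counts were 70 and 12, and no splits were run with it. In the HAR control library, at N2, 2xHAR.548 tile 2 had a human advantage of 1.07 and 2xHAR.401 a deficit of −0.56, nearer to Pt2A N3 than to Pt2A N2 of the HAR library, so the stage may not be the cause for these pairs.

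The Pt2A N2 activities of the HAR library stood apart from the other groups of that library and from the HAR control library. The tables argue against RNA carried into the DNA libraries, because over 2440 elements the RNA shift followed the DNA shift with a slope of 0.328 (SE 0.0115), where carried RNA needs a slope of at least 1. A shift in the Pt2A N2 DNA libraries is a candidate explanation, since the same RNA over Pt2A N3 DNA correlated with Pt5C N3, which shares no library with it, at 0.696, against 0.0377 over its own DNA. With the HAR control library this RNA over Pt2A N3 DNA reached 0.587, against 0.743 to 0.881 for the other groups over their own DNA. Such a shift may therefore explain only part of the pattern. A state of Pt2A cells at N2 stays open, because the values go both ways. The HAR control library of the same line and stage correlated with these activities at −0.109, but its DNA deviated from N3 DNA in the same way (r = 0.721 to 0.725, slope 0.494 to 0.502). All such deviations share the N3 DNA baseline. Those of Pt5C N2 replicates 1 and 2 gave 0.139 and 0.173, of Pt2A N3 0.403 to 0.463 and of Pt5C N3 −0.513 to −0.352. The permutation library at N2 correlated with these activities at 0.860, but its DNA shared the Pt2A N2 deviation at 0.93. Over N3 DNA in both the correlation was 0.74. With the HAR control library its N2 activity correlated at −0.00355, at −0.144 over 265 controls and at 0.788 over 173 HAR variants. The permutation library at N3 also correlated with Pt2A N2 at 0.733, and Pt5C N2 replicate 3, of the other line, shared the DNA deviation at 0.925.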

How the results depend on the processing

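N3 DNA as denominator, the spread between barcodes or variants as error, negative controls as centre, shuffled HARs as zero point, the mean without Pt2A N2 and every alternative for the allele differences of the HAR control library were chosen only after results were seen. The low-count filter removed no element, so its alternative is left out. Over the others, 1084 of the values of 105 named items kept direction and side of the threshold, 22 lost their call, 1 gained one and 7 reversed, and 212 counts of 23 results stayed within 1.5 times while 21 moved. Allele calls under other count models could not exceed those of the unchanged barcode test. Reversed were, with N3 DNA, the all-human variants at N2 of 2xHAR.65 tile 2 (−0.0059) and HAR34 (0.063) and the sites A88T (−0.0030) and C55T (0.00055) of 2xHAR.1, without the top barcode the all-human variants of 2xHAR.65 tile 1 at N2 (0.017) and 2xHAR.142 at N3 (−0.012), and with the median over barcodes a positive control class of 2 elements (−0.015). The barcode spread gave 314 active elements in Pt2A N2, 416 in Pt5C N2 and 581 in Pt2A N3, and the variant spread 9 sites. N3 DNA gave 11 allele calls in Pt2A N2, 673 line differences at N2 and 12 alleles by line. The mean without Pt2A N2 gave 26 pairs, shuffled HARs as zero 837 active elements, the median over barcodes 2 classes, and reciprocal overlap 27187 shared peaks. For each of these the cause was not tested.

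Without 1 culture, active elements ran from 528 to 595 in Pt2A N2, 580 to 906 in Pt5C N2, 761 to 831 in Pt2A N3, 801 to 921 in Pt5C N3 and 1324 to 1357 in the HAR control library. Allele calls ran from 28 to 45, 13 to 28, 15 to 23 and 19 to 22 in these 4 groups, 12 to 16 in their mean and 99 to 119 in the HAR control library. Stage differences ran from 1430 to 1525 in Pt2A and 246 to 518 in Pt5C, line differences from 1193 to 1629 at N2 and 423 to 507 at N3, alleles by stage from 69 to 108 and by line from 45 to 105. In the permutation library, stage differences ran from 45 to 317 and sites from 17 to 23, variants and HARE5 tiles passing both tests stayed at 0 (edgeR alone 193 to 383 at N2 and 1 to 7 at N3) and classes of the HAR control library at 1.

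The main edgeR fits did not take replicate numbers as pairs, since of 21 same-number correlations only 1 exceeded 0.1 (−0.136 to 0.103). Values per culture, with their SDs and sign counts, do set each RNA library over the DNA library of the same number. Of the 21 RNA libraries 12 were highest with their own number, against 7 on average when numbers are permuted (exact permutation p = 0.04, a test chosen after the result was seen), so weak pairing is not excluded. With a replicate block, stage differences numbered 1606 and 407, line differences 1403 and 549, alleles by stage 108 and by line 86, and permutation stage differences 219. No alternative varied the depth or the number of barcodes, so their limits were not compared.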

Other observations

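Of the tests in this part, the tests of site pairs, the GC content of shuffled sequences and the listing of the largest allele differences in the HAR control library were chosen only after results were seen, as were the settings with N3 DNA.

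The largest allele differences of the HAR control library, listed after their values were seen, were human gains in 2xHAR.548 tile 2 (1.07), 2xHAR.10 tile 1 (0.91) and 2xHAR.513 tile 2 (0.87), and human losses in 2xHAR.518 (−0.79), 2xHAR.511 (−0.72) and 2xHAR.385 tile 2 (−0.60). In the mean of the HAR library 2xHAR.513 tile 2 was at 0.15 and 2xHAR.511 at 0.034. Over the 150 shuffled HARs, DNA abundance followed GC content (r = 0.701, rho = 0.747, permutation p = 1e-05 for each, the smallest the resamples can give, adjusted p of r 2e-05 over 2 relations, r = 0.680 without the 2 farthest). Their activity did not (r = 0.0849, permutation p = 0.2997, rho = 0.0611, permutation p = 0.459, r = 0.0714 without the 2 farthest). Shuffled sequences are not independent replicates.

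The edgeR test called 458 pairs in the mean of the 4 groups, while 14 passed both tests. After barcodes were shuffled between the alleles of each pair, edgeR still called a median of 420 pairs (405 to 442 over 10 shuffles). Most of the 458 calls may therefore reflect differences between barcodes of 1 sequence. No biological explanation was tested for the excess. Named pairs such as 2xHAR.10 tile 1 and 2xHAR.518 passed the barcode test as well.

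Of 87 pairs of sites tested 3 were called, all in 2xHAR.1, A36T with A88T (−0.028) and C55T with A88T (0.028, adjusted p = 0.0239 each by the spread between variants), and A94G with G95C, with an interaction of 0.064 (SE 0.0082 over 512 variants). Against both sites chimpanzee, the human base at 94 alone gave −0.059 ± 0.021, at 95 alone 0.0044 ± 0.0067 and at both 0.0092 ± 0.015 (SD, n = 6 cultures). A few barcodes with high RNA are argued against, since the interaction was 0.0649 without the top barcode. With N3 DNA it was 0.026 (SE 0.0074, adjusted p = 0.0187 over 36 pairs), and it was 0.096 in N2 cultures and 0.031 in N3 cultures, so a shift in the N2 DNA libraries may explain part of it. The rest stays open, and its biological cause was not tested. The interactions of A36T with A88T and of C55T with A88T were not retested with N3 DNA. As single sites, A36T (0.0022), A88T (−0.0030) and C55T (0.00055) were not called with it.

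For the counts within single groups, the splits of the libraries are too few for a share under 0.05. Active elements numbered 679 in Pt2A N2, 892 in Pt2A N3, 919 in Pt5C N3 and 1370 in the HAR control library, where the highest other split gave 0, and 752 in Pt5C N2, where it gave 136. Pairs called by edgeR numbered 246 in Pt2A N2, 221 in Pt5C N2, 250 in Pt2A N3, 266 in Pt5C N3 and 399 in the HAR control library, and comparisons in the permutation library (760 variants and 8 tiles of HARE5) 284 at N2 and 39 at N3, against 0 in the highest other split. For the 458 pairs in the mean of the 4 groups, the splits swapped the human and chimpanzee labels within some cultures. The real labels alone gave as many calls (1 of 100 splits, highest other 82). For the 23 sites the real split alone gave as many (1 of 32 splits, highest other 17). Differences between barcodes or variants that all cultures share would also favour the real labels. These splits therefore show only that the effects repeat between cultures. For the 458 pairs this takes the Pt2A N2 DNA libraries as separate infections, which stays open. Splits of cultures do not test differences between barcodes or variants, which all cultures share, and edgeR called a median of 420 pairs after barcodes were shuffled, while 9 sites were called against the spread between variants.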
